A study of Mus musculus with 18 samples.

How the data were processed

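Total RNA from the end-stage splenic tumours of 18 mice was hybridised to Affymetrix arrays, 1 array per tumour, per the labels' protocols. The mice carried the Eμ-Myc transgene, in which an immunoglobulin heavy chain enhancer drives Myc in the B lineage, on a background that the labels give as C57BL/6. Of the tumours, 9 came from Prdm11 wild-type (WT) mice and 9 from Prdm11 knockout (KO) mice, and each came from a mouse with its own identity number. The tumours were frozen whole and homogenised, with no sorting of tumour cells stated in the labels' protocols. The replicate number in each title was used to name a tumour within its genotype.

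The deposited values were probe set intensities on a linear scale, made by the authors with RMA, per the submitters' processing notes. The version of RMA, the normalization reference and the genome build were not given in the sources used here. The deposited intensities ran from 1.63 to 14996, and the array medians from 35.3 to 41.7. The design written before the data were examined had assumed log2 values and foresaw a log2 transformation of linear ones. All values were therefore transformed to log2 with no pseudocount. Of 153 pairs of arrays, 0 held identical values, and at most 0.045% of probe sets had equal values between 2 arrays, so each array counted as 1 replicate.

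Probe sets were named through the platform annotation table supplied with the values. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. A probe set without a symbol there is unnamed here. Gene identifiers of 21698 named probe sets were matched to a RefSeq gene table on the GRCm38.p6 assembly, which changed 0 symbols. That table was used only for symbols, chromosome membership and the order of neighbouring genes. Each gene was represented by the probe set with the highest mean over the 18 arrays, which gave 19938 genes, and 999 of them had more than 1 probe set. No filter on dim probe sets was applied.

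Genes were compared between genotypes with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on log2 values with no covariate. P-values were adjusted over all 19938 genes by the Benjamini-Hochberg method, and an adjusted p below 0.05 counted as past the threshold. The level of Prdm11 was compared by a two-sided exact permutation test over all 48620 splits of the 18 tumours into 9 and 9, and Fos and Jun were given the same test. The smallest p this design can give is 4.1e-05. A total of 32 gene lists, covering B cell stages, other cell types of the spleen, growth, stress and metabolism, were fixed before the data were examined. For each list the mean log2 level over its measured members was taken in each tumour, the difference of group means was tested by the same exact permutation test, and p-values were adjusted over the 32 lists. Members were also adjusted over the list alone. Lists needed at least 5 measured members. Camera with a preset correlation of 0.01, camera with an estimated correlation, and fry were run on the same lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

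The genes named in the report followed a rule written before the data were examined. Prdm11 came first, followed by the 12 genes higher and the 12 genes lower in KO tumours. Those past the threshold were taken by size of change, and the places left were filled by smallest unadjusted p. Unannotated clones were passed over. Each list contributed up to 4 members past the threshold over all genes, or otherwise the 2 with the smallest p, and Fos and Jun were named whatever their values. Any other gene named was chosen after its values were seen.

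The limma steps were tested on simulated data of the same size, 9 against 9 tumours and 19938 genes, with 200 changed genes in each of 5 runs. They recovered 62.7% of genes changed 1.5-fold, 94% of those changed 2-fold and 97.6% of those changed 3-fold, with 4.2% false among the genes called. The simulated noise was independent between genes, which real tumours need not follow. These shares hold for 200 changed genes. Where fewer genes change, the Benjamini-Hochberg adjustment is stricter and a 2-fold change is more easily missed. The permutation test of lists was tested on 2000 simulated lists per shift, with an SD of 0.7 between tumours. An unadjusted p below 0.05 was reached by 5.1% of unshifted lists, by 29.8% of lists shifted by 0.5 on the log2 scale and by 81.4% of those shifted by 1.0, so that moderate shifts of lists this variable are often missed.

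Alternatives covered the choice of probe set, scaling by quantiles or by array medians, a filter on dim genes, the replicate number as a block, left-out tumours, the variance model, array weights, Xist level as a covariate (the labels give no sex), and cell composition covariates. List tests with covariates used 20000 permutations of residuals. Scan dates and batches were not given in the sources used here, so no comparison within batches was made. The number of arrays limits the precision of every value. Probe sets with several symbols or none were not used for named genes.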

Results

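Gene expression was measured in end-stage splenic lymphomas of Eμ-Myc mice, a model in which Myc is expressed in the B lineage and B cell tumours follow. The 18 tumours, from separate mice, formed 2 groups of 9 that differed in Prdm11 genotype. Prdm11 encodes a member of the PRDM family of PR domain proteins. The comparison asked which transcripts differed between tumours with and without Prdm11. Levels are log2 RMA intensities, given as mean ± SD over 9 tumours, and differences are KO minus WT. The array medians after RMA ran from 35.3 to 41.7. The array of WT tumour 3 stood furthest from the rest, with a median correlation of 0.924 to the other arrays against 0.957 to 0.976 for the remaining 17.

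The probe set for Prdm11 gave overlapping levels in the 2 genotypes. Its level was 5.33 ± 0.26 (SD, n = 9) in WT tumours and 5.21 ± 0.23 (SD, n = 9) in KO tumours, a difference of -0.12 (SE 0.12, two-sided exact permutation p = 0.311). Where this single probe set lies relative to the deleted part of the gene is not given in the sources used here, so it does not check the genotype labels. Its mean level also lay at percentile 46.2 among all genes, so a dim signal in both genotypes may limit this comparison. Fos and Jun encode core subunits of the AP-1 transcription factor. Fos averaged 4.98 ± 0.24 in WT and 4.77 ± 0.20 in KO tumours, a difference of -0.21 (SE 0.10, exact permutation p = 0.0555). Jun averaged 6.17 ± 0.25 and 6.04 ± 0.22, a difference of -0.13 (SE 0.11, exact permutation p = 0.249). Among all genes the mean level of Fos lay at percentile 34.6 and that of Jun at percentile 68.4.

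Cd59a was the 1 gene of 19938 past the adjusted threshold of limma in the main fit. Cd59a encodes a membrane-anchored inhibitor of the complement membrane attack complex. It averaged 7.22 ± 0.67 in WT and 5.19 ± 0.69 in KO tumours and fell by 2.03 on the log2 scale (SE 0.29), a 4.08-fold lower level, with an adjusted p of 0.0167 in limma. In 7 of 9 KO tumours Cd59a was below every WT tumour. Cd59b, its close paralog, averaged 5.23 ± 0.28 in WT and 4.52 ± 0.29 in KO tumours, a difference of -0.71 (SE 0.13, limma adjusted p = 0.164), and probe sets of these similar genes may share signal. Cd59a, Cd59b and Prdm11 all lie on chromosome 2 in the GRCm38.p6 gene table, with 45 measured genes between Prdm11 and Cd59a and 0 between Cd59a and Cd59b. In the same KO tumours the erythroid list had a shift of -0.55 (SE 0.25) and the pan-B list a shift of 0.39 (SE 0.14). The adjusted p of Cd59a moved to between 0.0525 and 0.0632 when WT tumour 3, 4, 5, 6, 7 or 9 or KO tumour 3, 5, 7 or 8 was left out. It was 0.129 without WT tumour 3 and KO tumour 4, the 2 arrays of lowest weight, a setting chosen after the data were seen, and 0 probe sets passed when all 35556 were tested without collapsing to genes.

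**Figure D1:**
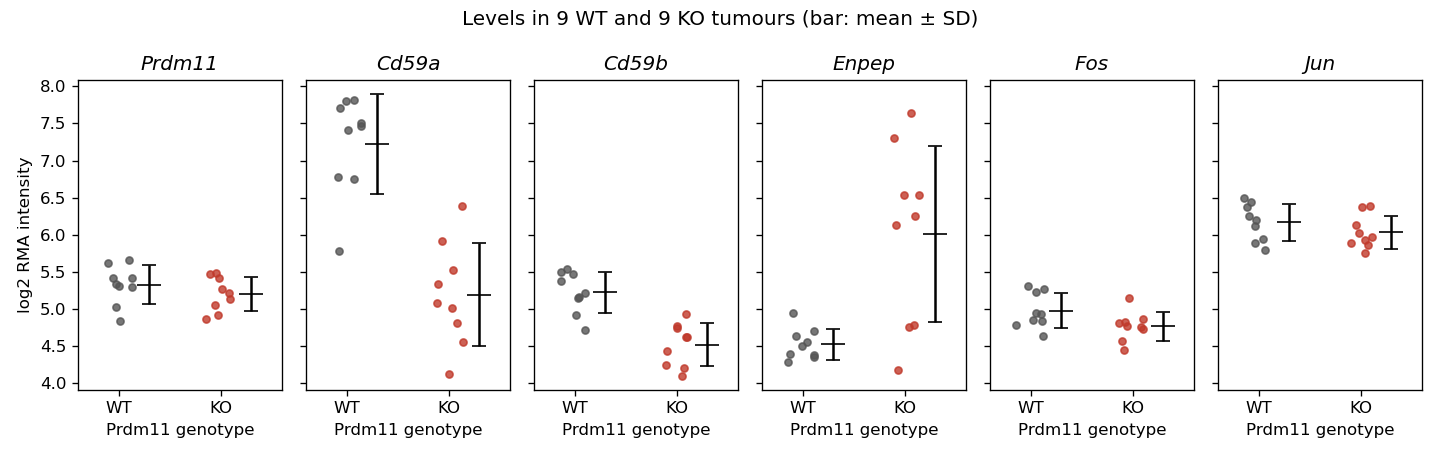
Log2 RMA intensity (vertical axis) of Prdm11, Cd59a, Cd59b, Enpep, Fos and Jun in each of the 9 WT (grey) and 9 KO (red) tumours, with bars for the mean ± SD. Cd59a averaged 7.22 in WT and 5.19 in KO tumours, while the Prdm11 values of the groups overlap and Enpep spans 4.18 to 7.63 among KO tumours.

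No gene was higher in KO tumours past the adjusted threshold of limma, and 564 were higher at an unadjusted p below 0.05. Among the 12 with the smallest p, Enpep had the largest difference. Enpep encodes glutamyl aminopeptidase, the BP-1 antigen of early B lineage cells. It averaged 4.53 ± 0.21 in WT and 6.01 ± 1.19 in KO tumours, a difference of 1.48 (SE 0.36, limma adjusted p = 0.504), and 6 of 9 KO tumours were above every WT tumour while 1 was below. Pde3b, a cyclic nucleotide phosphodiesterase, had a difference of 0.70 (SE 0.15, limma adjusted p = 0.389), with 8 of 9 KO tumours above every WT tumour. Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, had a difference of 0.66 (SE 0.16). Slc12a2, a sodium, potassium and chloride cotransporter, had 0.45 (SE 0.11), and Septin6, a cytoskeletal GTP-binding protein, had 0.49 (SE 0.12). St13, a cochaperone of Hsc70, had 0.50 (SE 0.13), and Ankrd28, a regulatory subunit of protein phosphatase 6, had 0.41 (SE 0.10). The differences were 0.48 for Bbx, 0.49 for Rnf157, 0.47 for Snx30, 0.38 for Rufy2 and 0.83 for Fndc9.

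Besides Cd59a, the genes lower in KO tumours numbered 0 past the adjusted threshold of limma, and 772 genes in all were lower at an unadjusted p below 0.05. Fam210b, which encodes a mitochondrial protein, averaged 7.76 ± 0.38 in WT and 6.75 ± 0.45 in KO tumours, a difference of -1.0 (SE 0.18, limma adjusted p = 0.164). It lies on chromosome 2, as do Prdm11, Cd59a and Cd59b, and its distance from Prdm11 is not given here. All 9 KO tumours were below all 9 WT tumours for Fam210b and also for Phlda2, an imprinted gene with a difference of -0.42 (SE 0.09). Chance gives such a complete separation in 0.0041% of genes, or 0.8 of 19938, and 2 were seen. Dnajb3, of the DnaJ cochaperone family, had a difference of -1.17 (SE 0.24), and Asb17, an ankyrin repeat and SOCS box gene, had -1.0 (SE 0.21). Ackr1, an atypical chemokine receptor found on erythroid and endothelial cells, had -0.74 (SE 0.16). Svbp, the partner of the vasohibin tubulin carboxypeptidases, had -0.56 (SE 0.12), and Cln8, a protein of the endoplasmic reticulum, had -0.62 (SE 0.14). The differences were -0.49 for Clgn, an endoplasmic reticulum chaperone, -0.60 for Ccdc71l and -0.49 for the olfactory receptor gene Olfr963. Some of these levels were dim. The WT means were 5.14 for Phlda2, 5.27 for Ackr1, 4.43 for Clgn and 4.25 for Olfr963. The array medians ran from 5.14 to 5.38 on the log2 scale, so these 4 differences may lie near background. The median difference of all genes was -0.03. After median centring the counts at an unadjusted p below 0.05 were 650 higher and 654 lower, and after quantile normalization 573 higher and 925 lower. More genes were higher than lower among genes with a mean above the median gene (460 and 344) and over all probe sets (1114 and 1057). The counts were 935 higher and 888 lower without WT tumour 2, 375 higher and 663 lower without WT tumour 4, 1439 higher and 1781 lower with composition covariates, 1117 higher and 1398 lower with array weights, and 1417 higher and 1171 lower with the erythroid list as a covariate, chosen after the data were seen.

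Genes shared by all B cell stages had a positive list shift. The pan-B list averaged 7.12 ± 0.30 in WT and 7.51 ± 0.28 in KO tumours, a shift of 0.39 (SE 0.14, exact permutation p = 0.0137, adjusted p = 0.399). All 14 measured members had positive differences, 9 of them at an unadjusted p below 0.05, and 0 passed over all genes or adjusted over the list alone. Plcg2, a phospholipase of B cell receptor signalling, had a difference of 0.46 (SE 0.15), and Ikzf3, which encodes Aiolos, had 0.57 (SE 0.21). The pan-B mean was above the WT median in 8 of 9 KO tumours. Without WT tumour 2 the shift was 0.47 with an adjusted exact permutation p of 0.0474 (0.0474 to 0.627 over all settings), so that this tumour decides the side of the threshold. The pan-B list was called by camera with a preset correlation, with adjusted p = 0.315 with an estimated correlation. The pro-B and pre-B list had a shift of 0.38 (SE 0.27, exact permutation p = 0.183), with 17 of 20 members positive. Vpreb3 had a difference of 0.85 (SE 0.36), and Akap12, a kinase scaffold, had 0.63 (SE 0.28). The pro-B and pre-B shift was 0.57 with the erythroid covariate and 0.24 without the 2 arrays of lowest weight. The preset camera test called this list too, with adjusted p = 0.617 with an estimated correlation. Mature B cell genes had a mean shift of -0.03 (SE 0.25, exact permutation p = 0.898) and a median member difference of 0.02, with Tnfrsf13c, the BAFF receptor, at 0.37 (SE 0.14) and Cd37, a tetraspanin, at 0.24 (SE 0.20). Single left-out tumours moved the mature B cell shift between -0.20 (KO tumour 6) and 0.06 (WT tumour 4). MHC class II genes had a shift of -0.19 (SE 0.36), with H2-DMa at -0.26 and H2-Oa at -0.23, and single left-out tumours moved it between -0.39 (KO tumour 6) and -0.02 (KO tumour 4). With composition covariates the MHC class II shift was 0.18 and the mature B cell shift 0.12, and with the erythroid covariate they were -0.32 and -0.19. Germinal centre and plasma cell genes had a shift of -0.06 (SE 0.10), with the transcription factor Irf4 at 0.36 and the BCMA gene Tnfrsf17 at -0.23, and a range of -0.11 (without KO tumour 6) to -0.009 (without KO tumour 4), and it turned to 0.02 with composition covariates and to 0.03 with the median over members. In these 5 lists 0 members passed over all genes.

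Markers of red cell precursors had the largest negative list shift. The erythroid list averaged 7.84 ± 0.61 in WT and 7.30 ± 0.44 in KO tumours, a shift of -0.55 (SE 0.25, exact permutation p = 0.0417, adjusted p = 0.444). With 1 tumour left out, this shift ran from -0.62 (KO tumour 3) to -0.39 (WT tumour 1). Its unadjusted permutation p was below 0.05 in 17 of 28 other settings, and the adjusted p ran from 0.272 to 0.784. All 13 members had negative differences, 8 of them at an unadjusted p below 0.05, and 3 passed adjusted over the list alone while 0 passed over all genes. These were Klf1, an erythroid transcription factor, with a difference of -0.68 (SE 0.21), Rhd, a blood group antigen, with -0.82 (SE 0.26), and Hemgn, with -0.79 (SE 0.26), the last named after its values were seen. The erythroid list was called by camera with a preset correlation, with adjusted p = 0.617 with an estimated correlation. Macrophage and monocyte genes had a shift of -0.19 (SE 0.15, exact permutation p = 0.199), with 18 of 20 members negative, among them the complement gene C1qc at -0.49 (SE 0.18) and the haem oxygenase Hmox1 at -0.33 (SE 0.15). NK and cytotoxic cell genes had a shift of -0.30 (SE 0.29, exact permutation p = 0.326), with Ifng, the interferon gamma gene, at -0.50 (SE 0.18) and Gzmb, granzyme B, at -0.60 (SE 0.33). Both lists were called by camera with a preset correlation, each with adjusted p = 0.919 with an estimated correlation. Neutrophil genes had a shift of -0.32 (SE 0.37) with 17 of 17 members negative, including Lcn2, lipocalin 2, at -0.77 and Ly6g at -0.52. T cell genes had a shift of -0.21 (SE 0.26), with Ctla4 at -0.42 and Cd3g at -0.77, and dendritic cell genes had -0.20 (SE 0.17), with Siglech at -0.44 and Bst2 at -0.31. Endothelial and stromal genes had a shift of -0.08 (SE 0.10), with the matrix gene Lum at -0.21 and the vascular addressin Madcam1 at -0.25. Megakaryocyte and platelet genes had a mean shift of -0.02 (SE 0.16) and a median member difference of 0.002, with Gp9 at -0.23 and Itgb3 at 0.18, and over all settings it ran from -0.09 (without WT tumour 9) to 0.09 (composition covariates). Several of these shifts moved either way with single tumours. Without KO tumour 6 they were more negative, at -0.45 for NK genes, -0.37 for T cell genes, -0.31 for dendritic cell genes and -0.16 for stromal genes. The unadjusted exact permutation p were then 0.118, 0.142, 0.0381 and 0.0431, and adjusted over the lists 0.315, 0.326, 0.197 and 0.197. The NK shift was -0.16 without WT tumour 4 and -0.19 without WT tumour 8. The T cell shift was -0.11, -0.14 and -0.10 without WT tumour 4, 5 and 8, and the neutrophil shift was -0.15 and -0.17 without WT tumour 4 and 5. The dendritic shift was -0.13 without WT tumour 5, and the stromal shift -0.04 without WT tumour 4. With the median over members the dendritic shift was -0.08 and the stromal shift 0.005. With composition covariates the shift was -0.08 for NK genes, -0.06 for dendritic cell genes and 0.04 for stromal genes. With the erythroid covariate it was -0.53 for NK genes, -0.32 for dendritic cell genes and -0.42 for T cell genes. KO tumour 6 had a T cell mean of 7.13, against 5.53 to 6.17 in the other KO tumours, and an erythroid mean of 6.56, the lowest of all 18.

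**Figure D2:**
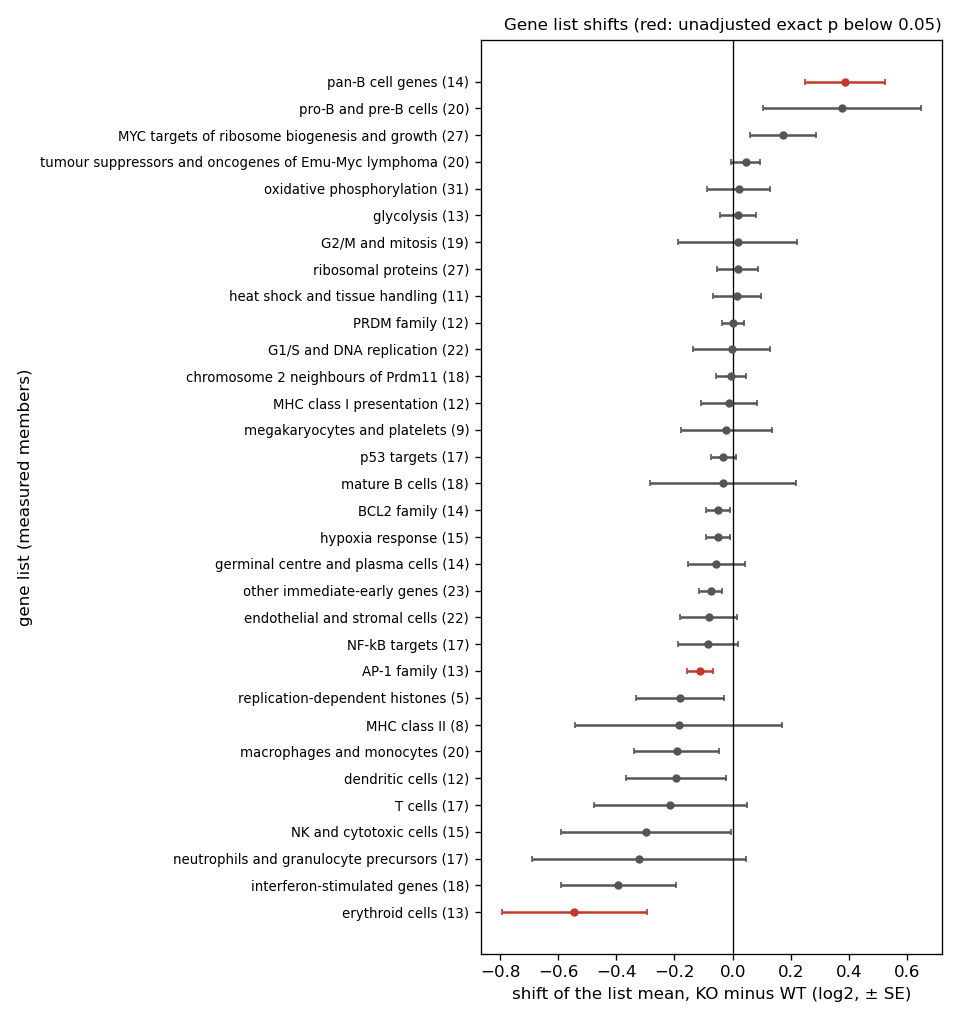
Shift of the mean log2 level, KO minus WT (horizontal axis, bars for ± SE over 9 and 9 tumours), for the 32 gene lists with the number of measured members in brackets. The pan-B list lies at 0.39, the pro-B and pre-B list at 0.38 and the erythroid list at -0.55, and the 3 lists with an unadjusted exact permutation p below 0.05 are red.

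Interferon-stimulated genes, which respond to antiviral cytokines, had a shift of -0.39 (SE 0.20, exact permutation p = 0.0662, adjusted p = 0.505), with 17 of 18 members negative and 6 of them at an unadjusted p below 0.05. Ifit1, an RNA-binding antiviral protein, had a difference of -0.87 (SE 0.28), and Rsad2, viperin, had -0.85 (SE 0.31). This list was called by camera with a preset correlation, with adjusted p = 0.617 with an estimated correlation. With the T cell, macrophage and erythroid lists as covariates the interferon shift was -0.02. The AP-1 family list had a shift of -0.11 (SE 0.05, exact permutation p = 0.0249, adjusted p = 0.399), with 11 of 13 members negative. Over all settings the AP-1 shift ran from -0.147 (erythroid covariate) to -0.084 (without the 2 arrays of lowest weight), and it was -0.086 without WT tumour 3. Mafk, a small MAF protein, had a difference of -0.27 (SE 0.09), and Batf3 had -0.22 (SE 0.11). The AP-1 mean was below the WT median in 8 of 9 KO tumours, and camera with a preset correlation called the list, with adjusted p = 0.617 with an estimated correlation. Other immediate-early genes had a shift of -0.08 (SE 0.04, exact permutation p = 0.079), with Ier3 at -0.39 and Klf4 at -0.27, and it was -0.02 with the median over members. Targets of NF-kB had a shift of -0.09 (SE 0.10), with the chemokine Ccl4 at -0.19 and the feedback inhibitor Tnfaip3 at 0.18, and over all settings it ran from -0.20 (erythroid covariate) to 0.002 (median over members). Heat shock genes had a shift of 0.02 (SE 0.08), which turned to -0.002 after quantile normalization, with Dnajb4 at -0.45 and Hspa8 at 0.18, and over all settings it ran from -0.29 (median over members) to 0.13 (composition covariates). In these 5 lists 0 members passed over all genes or adjusted over the list alone.

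Growth and proliferation lists had no shift past the threshold. MYC targets of ribosome biogenesis had a shift of 0.17 (SE 0.12, exact permutation p = 0.151), with 23 of 27 members positive, among them the growth regulator Pa2g4 at 0.42 (SE 0.16) and the RNA helicase Ddx21 at 0.45 (SE 0.18). Camera with a preset correlation called this list, with adjusted p = 0.617 with an estimated correlation. Ribosomal protein genes had a mean shift of 0.02 (SE 0.07) and a median member difference of -0.006, with Rps14 at 0.14 and Rpl30 at 0.22, and the shift ran from -0.02 (without WT tumour 3) to 0.05 (without KO tumour 4). DNA replication genes had a shift of -0.003 (SE 0.13), which was 0.02 after median centring, with Fen1 at -0.23 and Uhrf1 at 0.35. The replication shift was 0.12 with composition covariates (permutation p = 0.147), 0.22 with the erythroid covariate (permutation p = 0.0422, adjusted p = 0.262, with 0.262 to 0.999 over all settings) and 0.09 without KO tumour 6. Mitosis genes had a shift of 0.02 (SE 0.21), which was -0.01 after quantile normalization, with Nusap1 at -0.53 and Ccnb2 at -0.32. With composition covariates the mitosis shift was 0.28 (permutation p = 0.04, adjusted p = 0.29), and with the erythroid covariate 0.39 (permutation p = 0.0119, adjusted p = 0.0926, with 0.0926 to 0.999 over all settings), while it was -0.06 without the 2 arrays of lowest weight. Histone genes had a shift of -0.18 (SE 0.15), and 1 of 5 members, H2bc4 with a difference of -0.75 (SE 0.23), passed adjusted over the list alone, while H2aw had -0.32. The histone shift was -0.11 without WT tumour 1 or without KO tumour 4, -0.02 with the erythroid covariate and -0.34 with the median over members. Targets of p53 had a shift of -0.03 (SE 0.04), with Ddit4l at -0.26 and Sesn2 at -0.23. The p53 shift was -0.06 without KO tumour 6 and -0.02 without WT tumour 8, and it turned to 0.03 with composition covariates and to 0.04 among genes above the median level. With the median over members it was -0.16 (exact permutation p = 0.00675, adjusted p = 0.216, with 0.216 to 0.965 over all settings). The tumour suppressors and oncogenes of this model had a shift of 0.05 (SE 0.05), with the DNA damage kinase gene Atm at 0.39 and the p53 inhibitor Mdm4 at 0.28. That shift was 0.13 with composition covariates (permutation p = 0.00525, adjusted p = 0.0921) and with the erythroid covariate (permutation p = 0.00335, adjusted p = 0.0597, with 0.0597 to 0.962 over all settings), 0.07 without WT tumour 1 or 2, and 0.02 without WT tumour 3. BCL2 family genes had a shift of -0.05 (SE 0.04), with the anti-apoptotic Bcl2l1 at -0.38 and Bcl2l10 at -0.15. It was -0.08 without KO tumour 3 (unadjusted exact permutation p = 0.0369) and -0.001 with composition covariates.

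Metabolic and remaining lists gave shifts close to 0. Glycolysis genes had a shift of 0.02 (SE 0.06), with Pfkm at -0.16 and Slc16a3 at -0.11, and ran from -0.01 (composition covariates) to 0.10 (median over members). Hypoxia response genes had -0.05 (SE 0.04), with Adm at -0.27 and Bnip3l at -0.32. The hypoxia shift was -0.03 without KO tumour 3 or without KO tumour 4, -0.08 with the erythroid covariate, and turned to 0.08 with the median over members. Oxidative phosphorylation genes had 0.02 (SE 0.11), which was -0.003 after quantile normalization, with Ndufa6 at -0.24 and Atp5a1 at 0.21, and ran from -0.05 (median over members) to 0.07 (without KO tumour 4). MHC class I genes had -0.01 (SE 0.10), which was 0.006 after median centring, with B2m at -0.11 and Erap1 at 0.11, and ran from -0.05 (without KO tumour 6) to 0.11 (composition covariates). The other PRDM family genes had a mean shift of 0.001 (SE 0.04) and a median member difference of -0.02, with Prdm4 at 0.34 (SE 0.12) and Prdm6 at -0.28 (SE 0.10). The listed chromosome 2 neighbours of Prdm11 had -0.006 (SE 0.05), which was 0.01 after median centring, with Trp53i11 at 0.37 (SE 0.14) and Alx4 at -0.19. In these 6 lists 0 members passed over all genes or adjusted over the list alone.

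Across the 32 lists, 0 passed an adjusted p of 0.05 in the exact permutation test, and 3 had an unadjusted p below 0.05. Camera with a preset correlation called 8 lists, 0 of which held with an estimated correlation, and fry, which asks whether a list moves on balance one way, called 0. Leaving out 1 tumour moved the shift of 24 lists by over 1.5 times or turned its sign, and turned the sign of 11 with shifts from -0.03 to 0.02. Composition covariates turned the sign of 10 of the 29 lists they could be run on, the erythroid covariate that of 3 of 31, and the median over members that of 7 of 32. Lists of related cells share their variation between tumours, so their tests are not independent.

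Tumours of both genotypes varied widely in the list means of B cell stages and of other cell types, while cell shares were not measured. Mean MHC class II levels spanned 5.77 to 8.68 over the 18 tumours, a 7.51-fold range, and neutrophil genes spanned a 5.56-fold range. The spread between tumours did not separate the genotypes. The median log2 ratio of the SD in KO to the SD in WT tumours was -0.13, with the SD larger in KO tumours for 40.8% of genes, and it was 0.07 without WT tumour 3 and -0.24 without KO tumour 4. Of 100 splits of the tumours into 9 and 9, the real one included, 72 gave a ratio at least as far from 0.

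**Figure D3:**
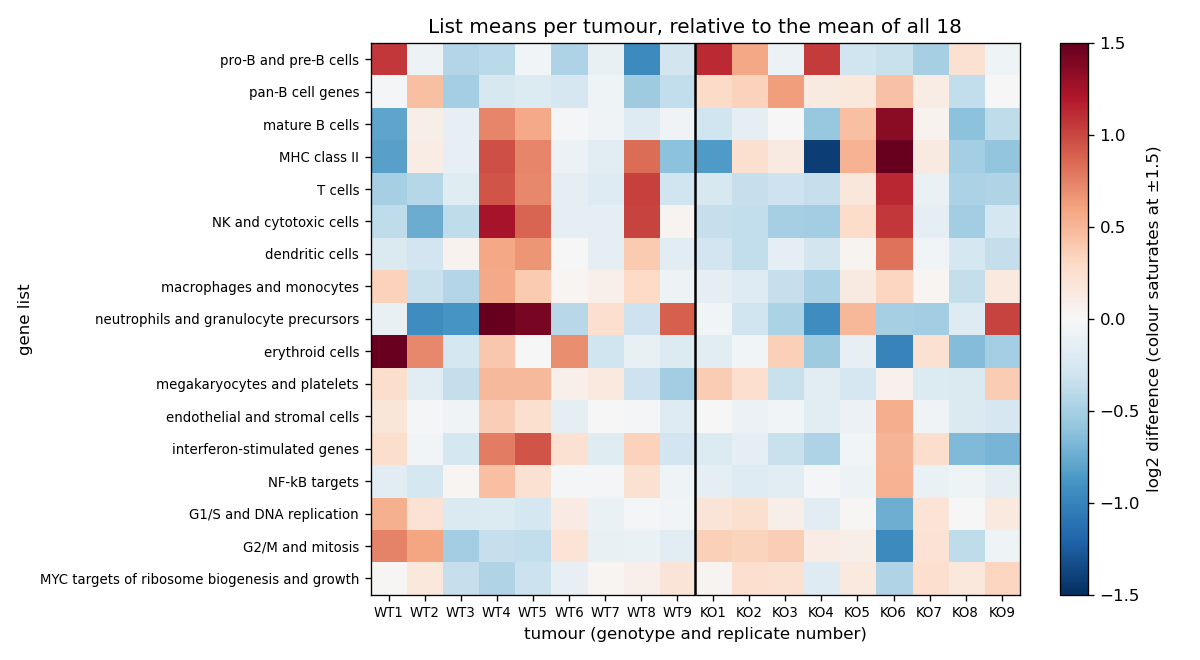
Mean log2 level of 17 gene lists (rows) in the 18 tumours (columns), each relative to the mean of all 18, with colour from blue (lower) to red (higher) that saturates at 1.5 either way. KO tumour 6 had the highest MHC class II mean at 8.68, and KO tumour 4 the lowest at 5.77.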

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

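The tests of the explanations for Cd59a and KO tumour 6 were chosen after their results were seen, as were the comparisons of gene counts with other splits and the erythroid covariate. Of 120 groups of 9 values, 14 had a tumour far from the others of its genotype, against 6 expected by chance at about 1 in 20, and 9 of the 14 were in KO tumour 6.

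KO tumour 6 stood above the other 8 KO tumours for markers of several non-tumour cells. It had a T cell mean of 7.13, an NK and cytotoxic cell mean of 6.56 (others 4.97 to 5.78), a dendritic cell mean of 5.77 (others 4.59 to 5.0) and an endothelial and stromal mean of 6.32 (others 5.52 to 5.77). NF-kB targets were at 5.82 (others 5.10 to 5.26), other immediate-early genes at 5.95 (others 5.63 to 5.76) and p53 targets at 6.07 (others 5.77 to 5.89), while DNA replication genes were at 7.17 (others 7.74 to 8.15) and Ankrd28 at 6.70 (others 7.19 to 7.63). More of every non-B cell type is argued against, since 6 of the 8 lists of such cells were higher and the erythroid list lay at -2.26 SD from the mean of the other KO tumours. A larger remnant of lymphoid tissue, with its T, dendritic and mature B cells, may still be present in this tumour and was not tested, nor was any explanation from the genotype.

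WT tumour 1 had a pro-B and pre-B mean of 7.64, against 5.61 to 6.53 in the other WT tumours, and an Rnf157 level of 5.95 (others 5.08 to 5.48). WT tumour 3 had a Slc12a2 level of 6.37 (others 6.74 to 7.09), a Phlda2 level of 5.66 (others 4.89 to 5.17) and an array median of 5.38 log2 (others 5.16 to 5.27).

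For the lower Cd59a in KO tumours, 3 of 100 splits, the real one included, called at least 1 gene, under the bound of 5 at which chance would stay open, but that bound was written down after the count was seen and 10 of 18 left-out tumours gave 0 called genes. The highest other split called 23 genes, several times the real count of 1, which points to a structure of the samples that was not tested further. Fewer erythroid cells in KO tumours would halve the difference once the erythroid list is a covariate, but it was then -2.30 (SE 0.31). Alleles of another strain carried along with the knockout could lower Cd59a without any role of Prdm11, since 0.46% of all measured genes lie as near to Prdm11 as Cd59a does, while the 45 genes between them had a median absolute moderated statistic at percentile 10.1 of 10000 random runs of neighbours and 8.9% of them an unadjusted p below 0.05, against 6.7% of all genes. Fam210b, also lower in KO tumours, is on chromosome 2 too, which holds 1737 of the 19938 measured genes. Its distance from Prdm11 is not given here. Linked alleles and loss of Prdm11 cannot be told apart here, because only some linked genes need differ between strains and every KO tumour carries the targeted allele.

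The 1336 genes at an unadjusted p below 0.05 exceed the 997 expected by chance, but chance is not excluded for this count: 31 of 100 splits, the real one included, gave as many, and the highest other split gave 3484.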

How the results depend on the processing

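The erythroid covariate, the small nucleolar RNA covariate and the omission of the 2 arrays of lowest weight were chosen after seeing the data. Cd59a was past the adjusted threshold of limma in 19 of 31 settings, with log2 differences from -2.30 to -1.82. The count of genes past it was 0 without the 2 arrays of lowest weight and ran from 0 to 1 over the 18 left-out tumours. Over all 35556 probe sets it was 0. There both the variance model and the adjustment cover all probe sets, and which of them ended the call was not tested. The replicate numbers did not pair the tumours: 4 of 9 same-numbered pairs correlated above 0.1 and 1 of 9 numbers matched best with itself. With the replicate number as a block the count was 0 and the adjusted p of Cd59a was 0.322. At an unadjusted p below 0.05 the count was 1336. That count was 804 among genes with a mean above the median gene, where fewer genes are tested, and 2171 over all probe sets, where more are. It was 3220 with composition covariates, 2588 with the erythroid covariate and 2515 with array weights, and the cause was not tested. Lists past the threshold numbered 8 with camera at a preset correlation and ranged from 0 to 1 over left-out tumours, and 0 under the other settings run. Of 954 recomputed list values, 100 changed sign while past no threshold and 1 came past it, the pan-B list without WT tumour 2. Of 799 recomputed values of named genes, 787 kept their direction and side of the threshold and 12, all of Cd59a, kept the direction only. The Prdm11 difference stayed negative in every setting run, with exact permutation p from 0.103 to 0.503. That filter gave no value for Prdm11, which lies at percentile 46.2 of mean level. The planned covariate from 3' and 5' control probe sets was not run, since those probe sets are not named in the tables used here. Signal over background was not used here, so how far dim probe sets limit these values is open.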

Other observations

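The test of the 8 non-B lists was written before its result was seen. The test of the pan-B list was chosen after, and the bound that decides it was reworded after its value was seen.

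Of 10 relations between gene lists across tumours, computed as one family, 6 had an adjusted permutation p below 0.05 for Pearson's r. After each genotype was centred on its mean, T cell and NK gene means correlated at r = 0.96 over 18 tumours (rho = 0.80, permutation p = 1e-05 for r, the smallest 100000 permutations can give, and 0.00011 for rho, adjusted p = 0.0001 and 0.0011), and r was 0.94 without the 2 tumours farthest from the median. T cell and interferon-stimulated gene means correlated at r = 0.78 (rho = 0.78, permutation p = 0.00028 and 0.00023, adjusted p = 0.0014 and 0.0011, r = 0.78 without the 2). Pro-B and pre-B genes ran against MHC class II genes, which mature B cells express, at r = -0.66 (rho = -0.59, permutation p = 0.0026 and 0.012, adjusted p = 0.0088 and 0.032, r = -0.58 without the 2). Neutrophil and macrophage genes correlated at r = 0.63 (rho = 0.59, permutation p = 0.0052 and 0.013, adjusted p = 0.012 and 0.032, r = 0.50 without the 2). MYC targets and mitosis genes correlated at r = 0.62 (rho = 0.43, permutation p = 0.0059 and 0.079, adjusted p = 0.012 and 0.13), and r was 0.36 without the 2 farthest tumours, so this relation rests on them. Pro-B and pre-B genes against mature B cell genes gave r = -0.52 (rho = -0.43, permutation p = 0.026 and 0.081, adjusted p = 0.044 and 0.13), and r was -0.37 without the 2, so that this relation also rests on them. The other 4 did not pass: pro-B and pre-B genes against mitosis genes gave r = 0.49 (rho = 0.31, permutation p = 0.04 and 0.2, adjusted p = 0.058 and 0.29, r = 0.22 without the 2). Erythroid against megakaryocyte genes gave r = 0.15 (rho = 0.14, permutation p = 0.55 and 0.59, adjusted p = 0.68 and 0.59, r = 0.17 without the 2). AP-1 against heat shock genes gave r = -0.12 (rho = 0.18, permutation p = 0.63 and 0.47, adjusted p = 0.7 and 0.59, r = 0.48 without the 2), and pro-B and pre-B against neutrophil genes gave r = -0.08 (rho = 0.15, permutation p = 0.76 and 0.57, adjusted p = 0.76 and 0.59, r = -0.06 without the 2).

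All 8 lists of non-B cells had negative shifts in KO tumours while the pan-B list had a positive one. The mean shift of the 8 lists was -0.23 (SE 0.14, exact permutation p = 0.125), and 15.1% of splits moved all 8 one way. A smaller share of non-B cells in KO tumours is a candidate explanation that these data leave open: the shifts did not move apart beyond chance (exact permutation p = 0.582 for their variance), while their mean did not pass a test. A positive pan-B shift produced only by fewer erythroid cells is argued against, since it was 0.53 with the erythroid list as a covariate, against 0.39 without.

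Nnt, higher in KO tumours at an unadjusted limma p of 0.000377, had overlapping values in the groups, 5.81 to 7.03 in WT and 6.42 to 7.46 in KO tumours.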
